A study of Microtus ochrogaster with 46 samples.

How the data were processed

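RNA was measured in tissue punches of the nucleus accumbens, a forebrain region of the reward system, from 46 prairie voles (Microtus ochrogaster). Per the labels' protocols, poly(A) RNA was made into unstranded libraries with random-hexamer priming, after synthetic spike-in RNAs had been added to each sample. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, fastp 0.14.1, FastQC 0.11.7, Salmon 0.12 and DESeq2, for which no version is named. The genome build and the annotation are not given in the sources used here.

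The authors deposited 1 table of 17479 genes by 46 libraries. Its values run from 0 to 19.9, and from the values themselves the authors' deposited unit is log2 of a normalized count plus 1. After the log was undone, the totals lay between 26.66 and 29.49 M (M for mega) in every library. The lowest values then fell on evenly spaced steps, each step being the value of 1 read in that library. Dividing each total by the value of 1 read gave an estimated depth of 15.3 to 37.8 M reads assigned to genes, with a median of 29.2 M. Among values of up to 3 reads, 50.6% to 91.8% per library (median 85.0%) lay within 0.1 of a whole number of reads. The remaining spread came with the gene, so the normalization held a gene-specific factor, whole reads were not recovered, and no count model was used. No spike-in row is in the table, and no column was without a sample.

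The gene-specific factors were read from values of up to 3 reads in 2719 genes, of which 2646 were too low to be tested, and correlated between libraries (337 or more shared genes per pair). Average-linkage clustering into a pair of clusters put 32 libraries in what is here called pattern A and 14 in pattern B. The patterns are defined from the data and are not study groups. The labels name no batch. With the untested genes alone 43 of 46 libraries kept their pattern, and the 3 that moved, from B to A, were all females of pattern B (24 h replicate 8, and 3 week replicates 3 and 7). The position of each library between the patterns was set to 0 at the median of pattern A and to 1 at the median of the male libraries of pattern B, and positions from separate parts of the genes correlated at r = 0.9 across females within groups.

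The rows carry gene identifiers, and 1 row carries a symbol, Avpr1a. The reference gene table used here (assembly MicOch1.0) matched 0 of the 17478 identifiers. The tests of the 30 gene lists fixed beforehand, the check of the sex labels by sex-linked genes, the cell type marker scores and the values of the other genes meant to be given always (Oxtr, Drd1, Drd2, Crhr1, Crhr2, Oprk1, Oprm1, Fos and Fkbp5) were therefore not run. No coordinates are given.

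Values were tested as log2(normalized count + 1), with a pseudocount of 1, in the 14455 genes with a mean normalized count of at least 10; 3024 genes were not tested. Fold changes are on that scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust empirical Bayes, in 1 fit of 6 group means over all 46 libraries, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. In all, 14 comparisons were made. The naming rule asked for symbols, which only Avpr1a has. Identifiers were therefore picked by the size part of the rule, as the 2 largest rises and the 2 largest falls among passing genes with a mean of at least 50, in the comparisons of 24 h with naive animals and in the comparison of the sexes over all conditions. Other tests used Python 3.11.15 with scipy 1.17.1: exact permutation tests of group differences, 100000 permutations within groups for correlations across libraries, and 100 permutations of the animals for correlations across genes. All tests were 2-sided.

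The limma step was tested on simulated data for all 14455 genes with seeded changes. For females at 24 h against naive females it recovered 66% of changes of 1.25-fold, 88% of 1.5-fold and 94% of 2-fold. For males at 24 h it recovered 28%, 64% and 90%. In each comparison 50 genes were seeded at each of 1.25-fold, 1.5-fold, 2-fold and 3-fold at once. With fewer changed genes the adjustment asks for a smaller unadjusted p, so recovery would be lower. The changes were seeded in genes with a mean of at least 50, and genes were drawn independently, so recovery in the real libraries may differ. No pair of libraries looked like 1 library entered more than once: over 5186 genes with a mean of at least 1000, the smallest SD of the log2 difference between libraries was 0.161, against 0.065 from counting alone at that mean.

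Before the data were examined, the alternatives listed were pseudocounts of 5 and 0.1, no filter and a mean of at least 100, quantile normalization, rescaling to the same total, a fit of only the groups compared, array weights, the replicate number as a block and leaving out each library in turn. After seeing the data, 4 more were added: a score of the genes that followed Avpr1a as a covariate, the estimated depth as a covariate, the normalization pattern as a term, and the libraries of pattern A alone. The replicate numbers come from the titles, and no label says that they mark a shared litter or batch.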

Results

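Prairie voles form lasting bonds between mates, and the study compared animals before pairing, early after pairing and after a longer time with a partner, in both sexes. The naive animals had lived for 3 weeks with a same-sex littermate. The paired animals had lived with an opposite-sex partner for 24 h or for 3 weeks. RNA-seq libraries of the nucleus accumbens came from 10 naive females, 10 females at 24 h, 9 females at 3 weeks, 6 naive males, 6 males at 24 h and 5 males at 3 weeks. These numbers follow the sample titles; the description of the series gives 6 females at 3 weeks. Estimated depth averaged 28.6 ± 6.38 M reads (M for mega; SD, n = 10) in naive females, 27.8 ± 2.37 (n = 10) in females at 24 h and 27.5 ± 6.24 (n = 9) in females at 3 weeks. In males it averaged 27.5 ± 5.22 M (n = 6) in naive animals, 27.8 ± 4.53 (n = 6) at 24 h and 31.6 ± 2.09 (n = 5) at 3 weeks. Intervals are not given for single genes, most of which carry an SD or an SE.

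The libraries differed in their gene-specific normalization factors in a way that followed some groups. All 6 naive males and all 5 males at 3 weeks, with 3 females (24 h replicate 8, and 3 week replicates 3 and 7), made up pattern B, while all 6 males at 24 h and the other 26 females made up pattern A. The factors of naive males correlated at a mean r of 0.65 with each other across genes and 0.59 with those of males at 3 weeks, but at -0.16 with those of males at 24 h. The factors of males at 24 h correlated at 0.27 to 0.31 on average with those of the female groups. On the scale from pattern A to the male libraries of pattern B, the 3 females stood at 0.34, 0.30 and 0.39, and clustering on untested genes alone put these 3 in pattern A. Comparisons among females, between males at 3 weeks and naive males, and between the sexes at 24 h therefore lie almost within a pattern. The comparisons of males at 24 h with the other male groups, and of the sexes in naive animals and at 3 weeks, run across patterns. In these the pattern and the group cannot be told apart. The only overlap is at 3 weeks, where 2 of 9 females were of pattern B, and these stood only part of the way.

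**Figure D1:**
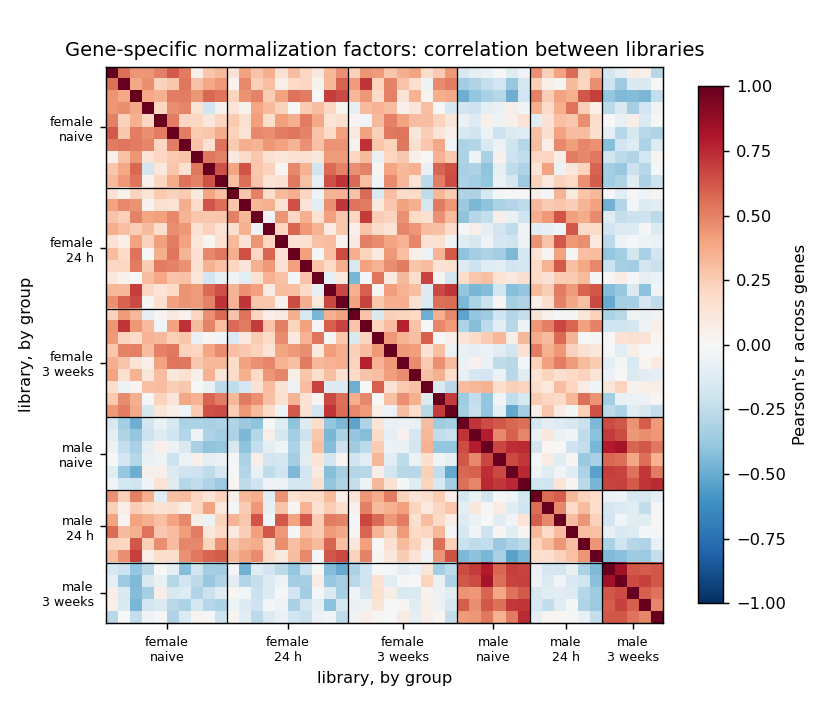
Pearson's r between the gene-specific normalization factors of each pair of the 46 libraries, in the order of the groups on both axes (black lines part the groups). Naive males and males at 3 weeks form 1 block (mean r of 0.59 between these groups), and males at 24 h fall with the females.

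Avpr1a, the vasopressin receptor 1a, which binds a peptide long studied in the social behaviour of voles, was higher in males than in females over the 3 conditions. The difference was 1.36 on the log2 scale (SE 0.38, 2.58-fold, adjusted p = 0.00891 by limma). Its mean log2 level was 5.90 ± 1.17 (SD, n = 10) in naive females, 5.44 ± 1.75 (n = 10) at 24 h and 5.07 ± 1.64 (n = 9) at 3 weeks. In males it was 6.61 ± 0.44 (n = 6), 6.91 ± 0.44 (n = 6) and 6.98 ± 0.70 (n = 5). Single conditions did not pass: the limma difference was 0.70 (SE 0.64, adjusted p = 0.572) in naive animals, 1.47 (SE 0.64, adjusted p = 0.36) at 24 h, where both sexes were of pattern A but for 1 female, and 1.92 (SE 0.69, adjusted p = 0.0956) at 3 weeks. With the normalization pattern as a term the difference over all conditions was 1.49, with an adjusted p of 0.0935. Time with a partner did not move Avpr1a past the threshold in either sex. Against naive animals the log2 difference was -0.46 (SE 0.55, adjusted p = 0.675 by limma) in females at 24 h and -0.84 (SE 0.57, adjusted p = 0.893) at 3 weeks. In males it was 0.31 (SE 0.71, adjusted p = 0.917) and 0.38 (SE 0.75, adjusted p = 0.999).

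Female levels of Avpr1a spread from 2.07 to 7.51 at 24 h and from 1.90 to 7.17 at 3 weeks, which is 3.21 to 181 and 2.74 to 143 normalized counts. Male levels at 24 h ran from 6.08 to 7.28. The mean distance from the group median was 1.32 in females and 0.29 in males at 24 h (exact permutation p = 0.0447, adjusted 0.101 over 6 tests of level and spread). In naive animals it was 0.91 and 0.30 (exact permutation p = 0.0671, adjusted 0.101), and at 3 weeks 1.26 and 0.50 (exact permutation p = 0.118, adjusted 0.142).

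**Figure D2:**
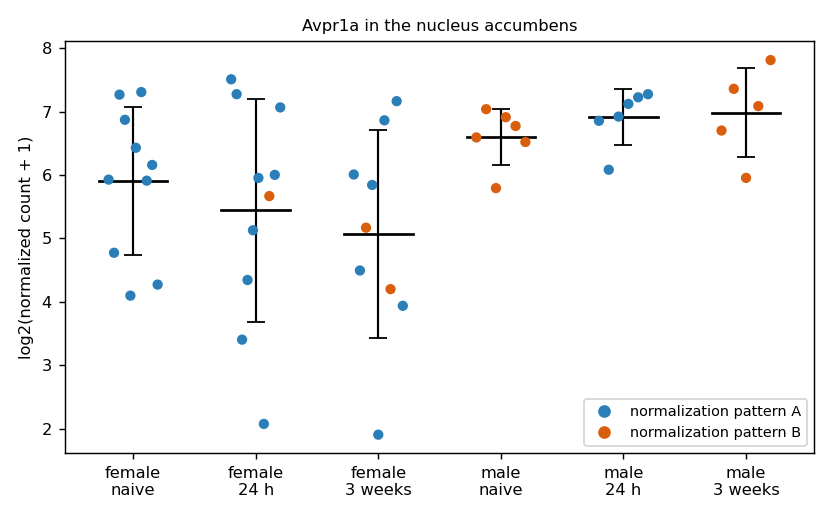
Avpr1a per library, as log2(normalized count + 1), in the 6 groups. Points are libraries, coloured by normalization pattern; lines and bars give the group mean and SD. Female libraries reach down to 1.90, while the lowest male library stands at 5.79.

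A group of 308 genes followed Avpr1a across females within groups (r of at least 0.7), and 215 genes ran opposite to it. These genes were picked on female libraries alone. In the 17 males, which took no part in the choice, 99.7% of the 308 genes also correlated positively with Avpr1a within groups, with a median r of 0.62 against 0 for all genes. A score of these genes tracked Avpr1a across the males within groups at Pearson's r = 0.81 (permutation p = 0.00024, adjusted 0.0012 over 5 relations) and Spearman's rho = 0.80 (permutation p = 0.00059). Without the 2 males farthest from the median score r was 0.84. Within the 11 males of pattern B r was 0.88 (permutation p = 0.001, rho 0.85), and within the 6 males of pattern A 0.75 (exact permutation p = 0.093, rho 0.71). Of the 308 genes, 306 had higher means in males than in females at 24 h (median log2 difference 0.36), and 242 passed the test as higher in males over all conditions, with 0 passing as lower. At 24 h against naive animals 0 of them passed in females and 1 in males.

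Between females at 24 h and naive females 15 genes differed (limma, adjusted p under 0.05), 5 higher and 10 lower at 24 h. All of them were small changes, with a median size of 0.35 on the log2 scale. Since the naive females had lived for 3 weeks with a same-sex littermate, pairing and a new cage mate cannot be told apart. ENSMOCG00000021620 fell from a mean log2 level of 8.31 ± 0.22 (SD, n = 10) to 7.84 ± 0.24 (n = 10), a change of -0.47 (SE 0.09, adjusted p = 0.0437), and stood at 8.24 ± 0.17 (n = 9) at 3 weeks. ENSMOCG00000014388 changed by -0.46 (SE 0.10, adjusted p = 0.0471), from 9.07 ± 0.28 to 8.61 ± 0.20, with 8.83 ± 0.23 at 3 weeks. ENSMOCG00000019919 rose by 0.28 (SE 0.06, adjusted p = 0.0471), from 10.77 ± 0.11 to 11.05 ± 0.18, with 10.90 ± 0.15 at 3 weeks. ENSMOCG00000016161 rose by 0.25 (SE 0.05, adjusted p = 0.0471), from 10.67 ± 0.10 to 10.92 ± 0.17, with 10.69 ± 0.13 at 3 weeks. At an unadjusted p under 0.05 there were 2802 genes, where 723 are expected by chance on average. The spread of that number among genes that move together was not measured, so the excess alone is no evidence of a change. The count sat at the edge of the threshold. It was 0 with no filter on low values, 0 in a fit of the 2 groups alone, and 0 to 476 when 1 library was left out. The call of ENSMOCG00000021620 was lost in 12 of 33 alternatives, and the calls of the other 3 genes in 16 each, at sizes close to those above. Among libraries of pattern A alone, an alternative chosen after seeing the data that leaves out female 24 h replicate 8 in this comparison, 170 genes passed, 110 higher and 60 lower, and these included all 15. Quantile normalization gave 14 higher and 11 lower.

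After 3 weeks with a partner no gene differed from naive females by limma (0 of 14455, 710 at an unadjusted p under 0.05), nor from females at 24 h (0, with 1248 at an unadjusted p under 0.05). The counts were 0 to 1 when a library was left out. Across genes, the changes at 24 h and at 3 weeks correlated at r = 0.57 in females, where unchanged groups against the same naive libraries gave a simulated mean of 0.49 (0.31 to 0.68). The covariance was 0.0253 against a simulated 0.0192 (0.0103 to 0.0361). When the naive females were split so that each change had its own 5 controls, r was 0.11, against a simulated 0.03. Genes are not independent replicates.

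In males 35 genes differed at 24 h from naive males by limma, 12 higher and 23 lower, with a median size of 0.29 on the log2 scale. ENSMOCG00000003872 stood at 9.46 ± 0.24 (SD, n = 6) in naive males and 8.73 ± 0.18 (n = 6) at 24 h, a change of -0.73 (SE 0.12, adjusted p = 0.00148). It was 9.38 ± 0.18 (n = 5) in males at 3 weeks and 8.79 ± 0.21, 8.83 ± 0.22 and 8.83 ± 0.22 in the naive, 24 h and 3 week females. ENSMOCG00000020904 changed by -0.64 (SE 0.13, adjusted p = 0.0126). ENSMOCG00000021288 rose by 0.66 (SE 0.10, adjusted p = 0.000533), from 9.74 ± 0.22 to 10.41 ± 0.22, with 9.74 ± 0.08 in males at 3 weeks and 10.35 ± 0.24 in naive females. ENSMOCG00000005535 rose by 0.65 (SE 0.14, adjusted p = 0.0215), from 8.18 ± 0.13 to 8.83 ± 0.15. All 6 naive males were of pattern B and all 6 males at 24 h of pattern A, so no value within a pattern exists. With the pattern as a term, which rests on the 3 females of pattern B, 0 genes passed by limma (1239 at an unadjusted p under 0.05); the median change of the 35 genes was 0.29 without the term and 0.34 with it, and their median SE 0.063 and 0.095. In a fit of the 2 male groups alone 2 genes passed, leaving out 1 library gave 14 to 60, array weights gave 187, and quantile normalization gave 12 higher and 39 lower.

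Of these 35 genes, 25 also differed between naive males and naive females, and 0 differed between the sexes at 24 h. These comparisons use the same 6 naive males or the same 6 males at 24 h that picked the genes, which favours the first count. With naive males set to 0 and males at 24 h to 1, naive females stood at a median of 0.80 (quartiles 0.64 and 0.92), females at 24 h at 0.84 and females at 3 weeks at 0.73. Males at 3 weeks stood at 0.15. These places also rest on the males that picked the genes, and reassigning the males to naive and 24 h gave naive females a place of 0.45 (0.18 to 0.74). When 35 genes were picked on 3 males of each group and placed on the other males, a test chosen after seeing the data, the change was 0.19 on the log2 scale (median of 100 draws, 0.05 to 0.34). Naive females then stood at 0.93, but with a range of -0.28 to 2.36.

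**Figure D3:**
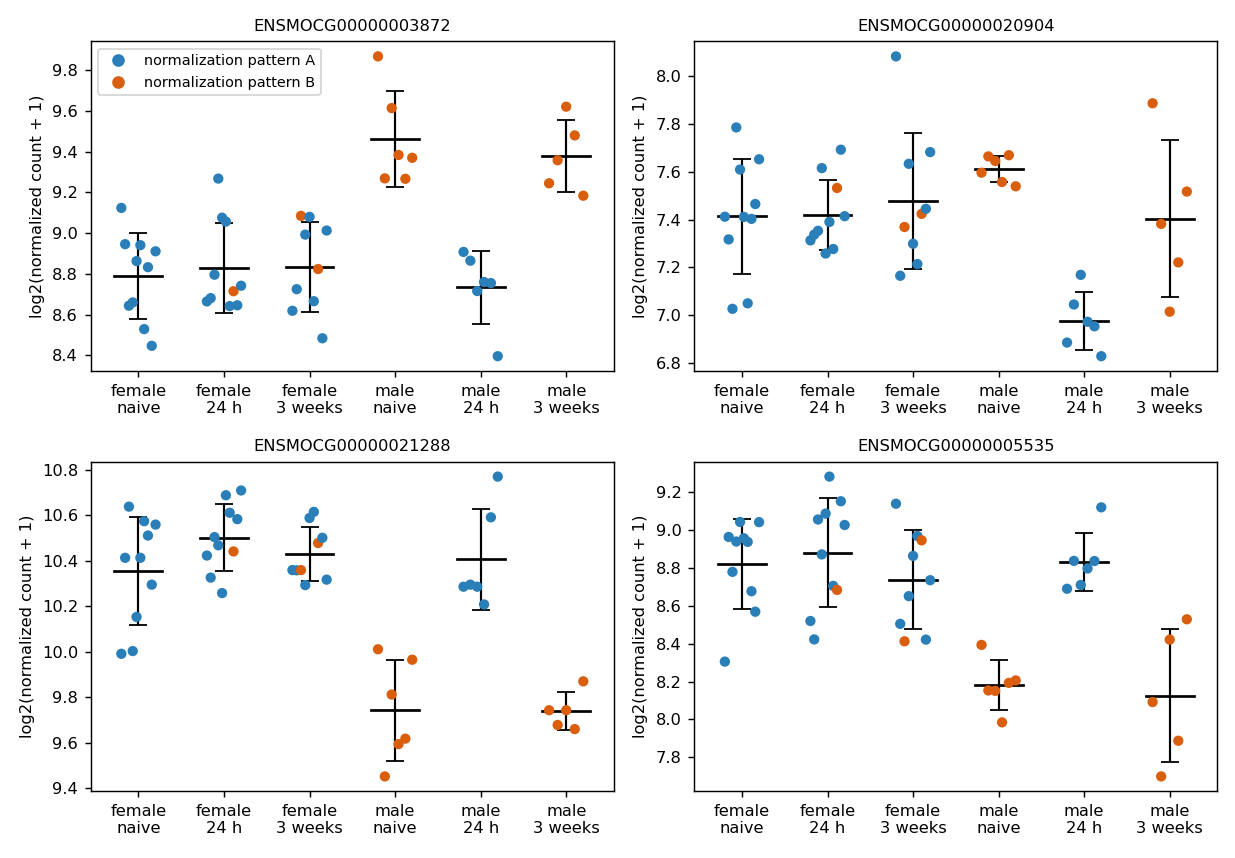
Levels per library, as log2(normalized count + 1), of the 4 genes named for males at 24 h. Points are libraries coloured by normalization pattern, and lines and bars give the group mean and SD. For ENSMOCG00000003872, ENSMOCG00000021288 and ENSMOCG00000005535 males at 24 h stand at the female level, and naive males and males at 3 weeks stand apart together; for ENSMOCG00000020904 males at 24 h (6.98 ± 0.12, n = 6) lie below every other group mean.

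No gene differed between males at 3 weeks and naive males, which share pattern B (limma, 0 of 14455, 344 at an unadjusted p under 0.05). In simulated data of that size 70% of changes of 1.5-fold and 92% of changes of 2-fold were recovered, with 50 genes seeded at each fold. Recovery would be lower if only a few genes changed, as each would then need a smaller unadjusted p. Between males at 3 weeks and at 24 h 10 genes differed, 3 higher and 7 lower at 3 weeks, and 8 of them were among the 35 genes above and went back in the opposite direction. Both comparisons use the males at 24 h. ENSMOCG00000021288 fell by 0.67 (SE 0.11, adjusted p = 0.00133 by limma). This comparison also runs from pattern A to pattern B, and 3 genes passed with the pattern as a term. Quantile normalization gave 7 higher and 9 lower, and rescaling libraries to the same total 11 and 11. In a fit of these 2 groups alone 0 passed (1465 at an unadjusted p under 0.05), and without male 24 h replicate 4 there were 20. The changes at 24 h and 3 weeks in males correlated across genes at r = 0.40, with a simulated mean of 0.45 (0.15 to 0.65) and a covariance of 0.0235 against a simulated 0.0292. With 3 separate naive males as controls for each change r was -0.05.

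Averaged over both sexes, 435 genes differed at 24 h from naive animals by limma, 238 higher and 197 lower, with a median size of 0.19 on the log2 scale. Leaving out 1 library gave 160 to 732. ENSMOCG00000013288 changed by -0.67 (SE 0.15, adjusted p = 0.0125), from 6.36 ± 0.43 (SD, n = 10) to 5.56 ± 0.24 (n = 10) in females and from 6.07 ± 0.36 (n = 6) to 5.52 ± 0.56 (n = 6) in males. ENSMOCG00000013535 changed by -0.58 (SE 0.14, adjusted p = 0.0228). ENSMOCG00000001604 rose by 0.70 (SE 0.18, adjusted p = 0.0282), from 5.93 ± 0.62 to 6.63 ± 0.52 in females and from 6.00 ± 0.71 to 6.70 ± 0.33 in males, and ENSMOCG00000000727 rose by 0.56 (SE 0.16, adjusted p = 0.0449), a call that 26 of 43 alternatives ended, with rises of 0.44 to 0.77. Of the 435 genes, 433 had the same sign in both sexes, as the averaging favours, and 10 passed in females alone and 25 in males alone. In their direction of change the median was 0.16 in females and 0.22 in males at 24 h, and 0.04 and 0.05 at 3 weeks. The naive and 24 h males differ in pattern, and with the pattern as a term 2 genes passed; the median change of the 435 genes was 0.19 without the term and 0.17 with it, and their median SE 0.047 and 0.06. Rescaling libraries to the same total gave 177 higher and 231 lower. At 3 weeks 0 genes passed when both sexes were averaged (508 at an unadjusted p under 0.05).

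No correlation of the 24 h changes of the sexes beyond chance was found across all genes (Pearson's r = 0.06, permutation p = 0.56, Spearman's rho = 0.16, permutation p = 0.26, 100 permutations of the animals), nor of the 3 week changes (r = 0.04, p = 0.67, rho = 0.03, p = 0.88 in the same permutation test). Of the genes called in each sex at 24 h, 0 were shared. Independent lists of these sizes would also share about 0, so this count does not tell the sexes apart. Of the 170 genes that passed in females of pattern A, 134 (78.8%) had the same direction in males, with a median male change of 0.08 in that direction. Of the 35 genes of males 23 had the same direction in females, with a median female change of 0.02. Neither of these counts was tested by permutation of the animals, and genes that move together can shift both by chance. The 24 h change itself differed between the sexes in 7 genes by limma. All 7 had lower means at 24 h than in naive males (median log2 change -0.48) and higher means in females (median 0.16), and 6 of them were among the 35 genes of males. ENSMOCG00000003872 was one, with a difference of -0.77 (SE 0.15, adjusted p = 0.0413). In a fit of the 4 groups alone 0 passed by limma (1264 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 11. With the pattern as a term 0 passed by limma (1904 at an unadjusted p under 0.05), and rescaling to the same total gave 1 higher and 7 lower. The 3 week change differed between the sexes in 0 genes (454 at an unadjusted p under 0.05).

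**Figure D4:**
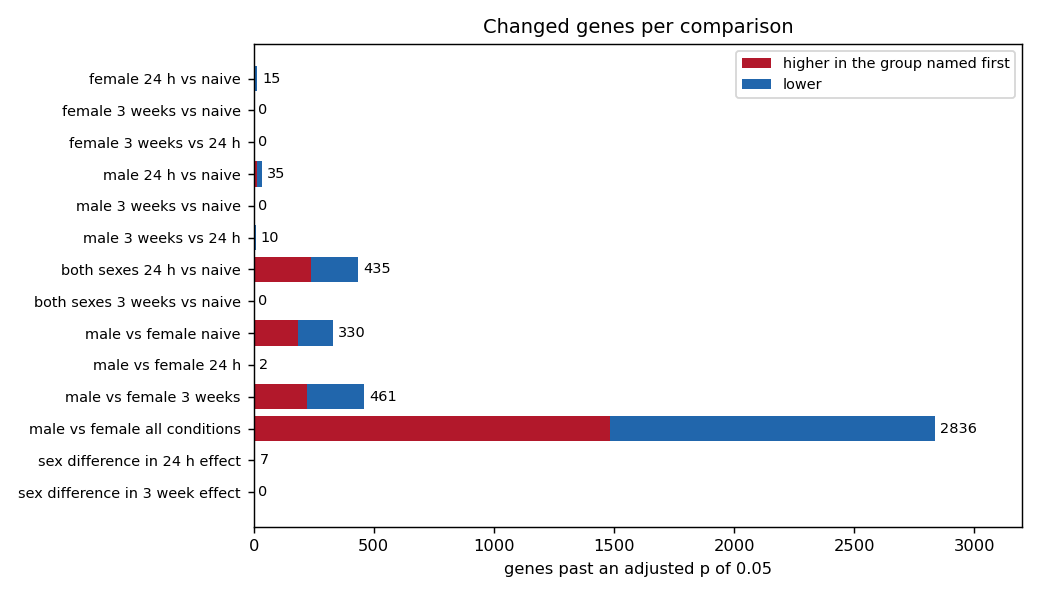
Number of genes past an adjusted p of 0.05 in each of the 14 comparisons, of 14455 tested, split into genes higher (red) and lower (blue) in the group named first; the last pair of bars counts genes whose change differed between the sexes. Sex over all conditions gave 2836 genes, and the 3 week comparisons with naive animals gave 0.

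Averaged over the conditions, 2836 genes differed between males and females by limma, 1482 higher and 1354 lower in males, with a median size of 0.22 on the log2 scale. ENSMOCG00000012222 was lower in males by 0.44 at 24 h (log2 difference -0.44, SE 0.05, adjusted p = 3.93e-07) and was the only gene of 14455 whose 17 male and 29 female libraries did not overlap, a share of 1.14e-12 by chance per gene. Its female libraries lay between 11.26 and 11.61 and its male libraries between 10.78 and 11.08. ENSMOCG00000013634 was higher in males by 0.91 at 24 h (SE 0.14, adjusted p = 0.00036). These were the 2 genes called at 24 h and were chosen for naming after their values were seen; both differed with the same sign in naive animals and at 3 weeks. The largest differences over all conditions came from genes that varied widely within groups. ENSMOCG00000020959 was higher in males by 1.74 (SE 0.34, adjusted p = 0.000477), ENSMOCG00000004048 differed by -2.12 (SE 0.75, adjusted p = 0.0413), a call lost in 22 of 56 alternatives at -2.12 to -1.81, and ENSMOCG00000017266, which was listed at 0 in 1 naive male and 1 male at 3 weeks, by -1.87 (SE 0.55, adjusted p = 0.0132). ENSMOCG00000009195 (adjusted p = 0.00724) was listed at 0 in 7 of 10 naive females, 5 of 10 females at 24 h, 5 of 9 females at 3 weeks and 4 of 6 males at 24 h. It was above 0 in all 6 naive males and all 5 males at 3 weeks, which are the males of pattern B, at 6.07 to 8.70. Rescaling libraries to the same total gave 1897 higher and 962 lower. With the pattern as a term 1366 genes passed, and with the Avpr1a-associated score as a covariate 228, fewer than the 690 for both sexes at 24 h in that fit. The 228 did not include the 4 genes of largest difference (adjusted p = 0.233 to 0.368). Their differences with the covariate were -2.09 for ENSMOCG00000004048, -1.28 for ENSMOCG00000017266, 1.91 for ENSMOCG00000009195 (3.28 without it) and 0.54 for ENSMOCG00000020959.

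In naive animals 330 genes differed between the sexes, 185 higher and 145 lower in males, and at 3 weeks 461 differed, 221 higher and 240 lower, all by limma; rescaling to the same total gave 414 higher and 143 lower at 3 weeks. At 24 h 2 genes differed (1663 at an unadjusted p under 0.05). Of the naive and 3 week genes 103 were shared, all in the same direction (59 higher and 44 lower, where independent lists would share 2.8 and 2.4). No library was common to these comparisons, but both run across patterns, and genes that move together also raise such an overlap. Both also involve the axis that Avpr1a marks. With its score as a covariate, genes outside the score went from 316 to 129 in naive animals and from 288 to 17 at 3 weeks. The 330 genes of naive animals had the same direction in 98.8% of cases at 3 weeks, with a median difference of 0.23, and in 70% at 24 h, with a median of 0.06. The 461 genes of 3 weeks had the same direction in 91.5% at 24 h, with a median of 0.15. Across all genes the sex differences of naive animals and of 3 weeks correlated at r = 0.54 (permutation p = 0.01, the smallest that 100 permutations can give, adjusted 0.03), those of naive animals and 24 h at 0.26 (permutation p = 0.03, adjusted 0.03) and those of 24 h and 3 weeks at 0.37 (permutation p = 0.02, adjusted 0.03).

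As a score per library, the mean signed level of the 330 naive genes was 0.232 ± 0.073 (SD, n = 5) in males and -0.074 ± 0.063 (n = 9) in females at 3 weeks (exact permutation p = 0.0005, the smallest that 2002 arrangements can give, adjusted 0.00225 over 6 tests). At 24 h it was 0.011 ± 0.040 (n = 6) and -0.063 ± 0.076 (n = 10), with an exact permutation p of 0.0456 (adjusted 0.0547). The difference between the sexes was larger at 3 weeks than at 24 h by 0.232 (exact permutation p = 0.00266, adjusted 0.00532). The score of the 461 genes of 3 weeks was 0.112 ± 0.116 (n = 6) in males and -0.086 ± 0.143 (n = 10) in females at 24 h (exact permutation p = 0.0145, adjusted 0.0217), with both sexes of pattern A but for 1 female. In naive animals it was 0.187 ± 0.078 (n = 6) and -0.106 ± 0.14 (n = 10), with an exact permutation p of 0.000749 (adjusted 0.00225), and its sex difference there exceeded that at 24 h by 0.095 (exact permutation p = 0.27, adjusted 0.27). Naive males and males at 3 weeks were of pattern B, and of the females at these times 2 were. With the pattern as a term 8 genes passed in naive animals and 233 at 3 weeks. Leaving out male naive replicate 1 gave 114 genes in naive animals, and leaving out male 3 week replicate 2 gave 92 at 3 weeks. At 24 h 97 genes passed without female 24 h replicate 1.

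**Figure D5:**
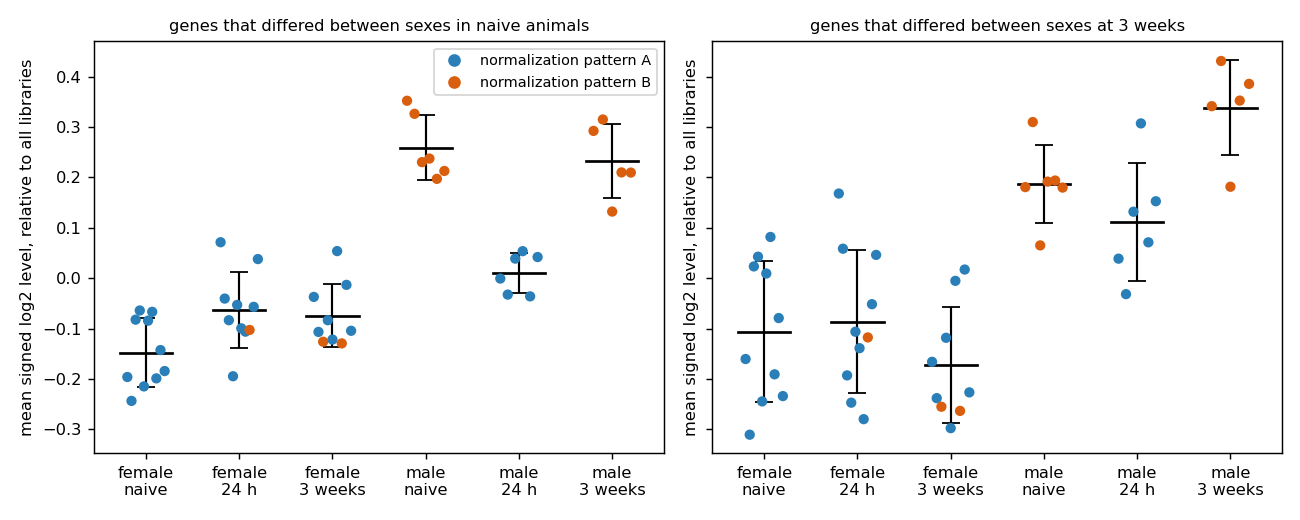
Mean signed log2 level of the 330 genes that differed between the sexes in naive animals (left) and of the 461 genes that differed at 3 weeks (right), relative to the mean of all libraries. Points are libraries coloured by normalization pattern, and lines and bars give the group mean and SD. The naive males on the left and the 3 week groups on the right were used to choose the genes; the males at 24 h stand at 0.011 ± 0.040 on the left.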

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

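The tests of the gene-specific normalization by library position were fixed before their results were seen; the tests of Avpr1a, of a library batch, of tissue sampling, of depth and of the splits of the samples were chosen after the results they bear on.

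The change at 24 h differed between the sexes in 7 genes by limma, among them ENSMOCG00000003872 (difference -0.77), and the sex difference of the score of the naive genes was larger at 3 weeks than at 24 h by 0.232 (exact permutation p = 0.00266). For the score of the 3 week genes the excess in naive animals over 24 h was 0.095 (exact permutation p = 0.27). These are differences between groups under the same contrast.

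Single libraries stood far from their group in 9 of the 144 groups of values examined, where chance gives about 7.2 (1 in 20). ENSMOCG00000004048 was 3.56 in naive female replicate 3 (median of the others 8.16) and 8.45 in male 3 week replicate 2 (median of the others 3.17). ENSMOCG00000013288 was 4.96 in female 24 h replicate 1 (others 5.6). Avpr1a was 6.08 in male 24 h replicate 2 (others 7.12), and ENSMOCG00000017266 was 0.92 in male 24 h replicate 4 (others 6.26). Male 24 h replicate 6 stood apart in ENSMOCG00000005535 at 9.12 (others 8.8) and in ENSMOCG00000012222 at 10.8 (others 11.02). It also stood apart in the spread of the values of 1 read, at 0.062 log2 (others 0.021), as did female 3 week replicate 1 at 0.097 (others 0.031).

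The first pattern is the change at 24 h. In females only 1 library of this comparison, 24 h replicate 8, was of pattern B. Without the libraries of pattern B 170 genes passed, a count reached in 1 of 100 splits of the rest with 2 genes in the highest other split. This argues against that library as the source of the change, but tests no other batch. Of the single libraries left out, replicate 8 raised the count most (to 476), and some others lowered it to 0. The 3 females of pattern B moved to pattern A when untested genes alone were clustered. In males the gene-specific normalization as a graded effect is argued against. Across females the score of the 35 genes had a reversed slope of -0.069 (SE 0.059) on the position of the library, where at least 0.185 was needed. The positions had a reliability of 0.95, but in females they ran only from -0.17 to 0.39. An effect that arises only nearer the males of pattern B (0.75 to 1.15) is not covered. With the pattern as a term the median change of the 35 genes went from 0.29 to 0.34 and their median SE from 0.063 to 0.095, so the calls ended through lost precision, but the 3 females behind that term stand only at 0.30 to 0.39 of the way to the males of pattern B. A library batch of naive and 3 week males and a change in paired males cannot be told apart: with genes picked on 3 males of each group and placed on the others, naive females stood at a median of 0.93 between naive and 24 h males, with a range of -0.28 to 2.36 that holds both.

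The second pattern is that more genes differed between the sexes in naive animals (330) and at 3 weeks (461) than at 24 h (2). With depth as a covariate 322 genes differed in naive animals (117 to 449 with 1 library left out), 4 at 24 h (2 to 74) and 233 at 3 weeks (46 to 641), so depth is argued against in naive animals and stays open for the count at 3 weeks, although the median size of the 461 genes there went only from 0.40 to 0.39. For the axis that Avpr1a marks, its score was a covariate and its own genes were left out. Then 129 genes differed in naive animals (41 to 190), 2 at 24 h (2 to 3) and 17 at 3 weeks (11 to 28). A score that follows the axis only in part leaves such genes, so these counts cannot decide whether the axis is the whole. The 316 genes called in naive animals without the covariate went from a median size of 0.31 to 0.27 with it. The 288 genes called at 3 weeks without it went from 0.37 to 0.26, at a median SE of 0.088 and 0.089. The graded normalization effect is argued against by a slope of -0.117 (SE 0.093) where at least 0.204 was needed. The libraries behind that slope stand at positions of -0.20 to 0.39. An effect that arises only nearer the males of pattern B (0.75 to 1.15) is not covered by it. A library batch is argued against as the whole sex difference for the 3 week genes only. They differed by 0.198 at 24 h (exact permutation, adjusted p = 0.0217), where the sexes share a pattern but for 1 female. Whether that difference lies on the axis that Avpr1a marks was not tested. The score of the 3 week genes and the Avpr1a-associated score were highest, and lowest, in the same 24 h libraries of each sex. Female replicates 1 and 7 had 0.168 and -0.280 for the former and 3.14 and -3.07 for the latter. Male replicates 4 and 2 had 0.307 and -0.032, and 3.10 and -0.41. A part of the difference at 24 h along that axis therefore stays open. The naive genes differed by 0.074 there (exact permutation, adjusted p = 0.0547), so for them a batch stays open. For the smaller difference at 24 h (0.232) batch and pairing cannot be told apart. Among males only those at 24 h have pattern A, and only 2 females at 3 weeks have pattern B. These 2 scored -0.126 and -0.130 for the naive genes, but stand only at 0.30 and 0.39 between the patterns. The 3 week genes showed no such excess in naive animals beyond chance (0.095, exact permutation p = 0.27).

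The third pattern is the wide spread of Avpr1a among females. Counting noise of Avpr1a alone is argued against, because 523 other genes correlated with it at an absolute r of at least 0.7, while shuffled orders gave at most 36 (share 0.001, the smallest that 1000 shuffles can give). A shared axis of sampled tissue, such as punches that held different parts of the region, is consistent with the correlation of 0.81 across males, which were not used to choose the genes. Coordinated differences between individual animals would give the same correlation and stay open, as does a true sex difference along this axis. With the score as a covariate the genes that differed by sex outside the score went from 2261 to 196, and the median size of the 2261 genes went from 0.20 to 0.12 with a median SE of 0.066 before and 0.073 after.

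Chance regroupings were counted over 100 splits of the same libraries, the real one included. The 15 genes of females at 24 h were reached in 2 splits (adjusted share 0.033 over 15 tests, highest other 374). With 100 splits that share is itself uncertain, and the count fell to 0 without some single libraries. Chance is therefore not firmly excluded for the 15 genes. The 2 genes of the sexes at 24 h were reached in 4 splits (share 0.04, adjusted 0.06, highest other 751), so chance is not excluded for this count after adjustment, though it is for ENSMOCG00000012222, whose male and female libraries did not overlap. The splits with 374 and 751 genes point to a structure of the samples: they parted the libraries by the Avpr1a-associated score, by 1.16 and 1.6 SD, the largest of 99 drawn splits in each case (medians 0.33 and 0.35). Chance can be excluded for males at 24 h (35, highest other 3, though 2 passed in a fit of the 2 groups alone) and both sexes at 24 h (435, highest other 91). The same holds for the sexes in naive animals (330, highest other 31) and over all conditions (2836, highest other 4). Each was reached in 1 split, the fewest possible. For males at 3 weeks against 24 h (10, highest other 5) and the sex difference of the 24 h change (7, highest other 2) the margin is thin, though each was also reached in 1 split. Both counts fell to 0 in a fit of the groups compared alone, and the second also fell to 0 without some single libraries. For the sexes at 3 weeks (461, reached in 1 split) the highest other split gave nearly as many, at 437. The count also fell to as few as 92 with 1 library left out, so chance is not firmly excluded for it. For the 5 comparisons with 0 genes all 100 splits reached the count, as any split must, so chance cannot be excluded by it. Their highest other splits were 52 for females at 3 weeks, 480 for females at 3 weeks against 24 h (a score difference of 0.26 SD, median of splits 0.29), 3 for males at 3 weeks, 4 for both sexes at 3 weeks and 1 for the sex difference of the 3 week change.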

How the results depend on the processing

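Tests with the covariates for the Avpr1a-associated score and for depth, the pattern term and the libraries of pattern A alone were chosen after seeing the data; the cause of a change in count was not tested unless stated. Pseudocounts of 5 and 0.1 kept all 14 counts of changed genes within 1.5 times. Of the values of single named genes under the alternatives, 977 kept their direction and side of the threshold, 136 kept the direction and lost the threshold, 2 passed it newly and 9 changed sign, all 9 of Avpr1a. Cell type marker scores and all gene list alternatives were not run, since the identifiers have no names, and the replicate block was not run for male against female comparisons because numbers are nested in sex. Of simulated changes of 1.5-fold at 24 h 64% were recovered in males (n = 6) and 88% in females (n = 10); depth was not varied there.

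With no filter on low values the counts were 0 for females at 24 h (2961 at an unadjusted p under 0.05; the adjusted p of ENSMOCG00000021620 was 0.056), 1 for females at 3 weeks against naive, 1 for females at 3 weeks against 24 h and 1 for the sex difference of the 24 h change. A mean of at least 100 gave 34 for females at 24 h and 18 for males at 3 weeks against 24 h, quantile normalization 25 and 16, and rescaling to the same total 24 and 22. The splits into higher and lower moved by over 10 points under quantile normalization for females at 24 h (14 and 11), males at 24 h (12 and 39) and males at 3 weeks against 24 h (7 and 9). Under rescaling they did so for males at 3 weeks against 24 h (11 and 11), both sexes at 24 h (177 and 231), the sexes at 3 weeks (414 and 143) and over all conditions (1897 and 962), and the sex difference of the 24 h change (1 and 7). With only the groups compared in the limma fit, 0 genes passed for females at 24 h (2541 at an unadjusted p under 0.05), 2 for males at 24 h, 0 for males at 3 weeks against 24 h (1465), 134 for the sexes in naive animals and 0 for the sex difference of the 24 h change (1264). Array weights gave 34 for females at 24 h, 1 for females at 3 weeks against 24 h, 187 for males at 24 h, 1 for males at 3 weeks, 93 for males at 3 weeks against 24 h, 653 for both sexes at 24 h, 545 for the sexes in naive animals, 86 at 24 h and 2157 at 3 weeks, and 20 for the sex difference of the 24 h change.

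The replicate numbers did not pair the libraries: same-numbered libraries correlated at a mean of 0.009 in females (-0.22 to 0.30) and -0.015 in males (-0.17 to 0.19), and in 6 of 56 comparisons of a female library with another female group, and 5 of 32 in males, its best match was its own number. With the replicate block the counts were 0 for females at 24 h (2905 at an unadjusted p under 0.05) and 16 for the sex difference of the 24 h change, and the other 8 counts it could be run for stayed within 1.5 times.

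With the Avpr1a-associated score as a covariate the counts were 140 for females at 24 h, 2 for females at 3 weeks against 24 h, 101 for males at 24 h, 22 for males at 3 weeks against 24 h, 690 for both sexes at 24 h, 141 for the sexes in naive animals, 20 at 3 weeks, 228 over all conditions and 13 for the sex difference of the 24 h change. Depth as a covariate gave 1 for males at 3 weeks, 18 for males at 3 weeks against 24 h, 4 for the sexes at 24 h and 233 at 3 weeks. The pattern term gave 85 for females at 24 h, 0 for males at 24 h (1239 at an unadjusted p under 0.05), 3 for males at 3 weeks against 24 h, 2 for both sexes at 24 h, 8 for the sexes in naive animals, 233 at 3 weeks and 1366 over all conditions, and 0 for the sex difference of the 24 h change (1904). Pattern A alone gave 170 for females at 24 h, 1 for females at 3 weeks against 24 h and 4 for the sexes at 24 h. The correlations of 24 h and 3 week changes went from 0.57 to 0.11 in females and from 0.40 to -0.05 in males with separate naive libraries for each change, a step that removes the shared controls.

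Leaving out 1 library at a time gave 0 to 476 genes for females at 24 h. There each of the 20 libraries moved the count by over 1.5 times: naive replicates 3, 5 and 6 raised it to 147, 37 and 155, 24 h replicates 2, 4, 7 and 8 to 40, 27, 51 and 476, naive replicates 2 and 8 lowered it to 3 and 1, 24 h replicates 5 and 9 to 2 and 8, and the other 9 to 0. The range was 0 to 1 for females at 3 weeks against naive (1 without naive replicates 6 or 9), against 24 h (1 without 24 h replicate 1 or 3 week replicates 7 or 9) and for males at 3 weeks (1 without naive replicate 5 or 3 week replicate 2). It was 14 to 60 for males at 24 h (naive replicates 1, 2, 3 and 5 gave 15, 23, 19 and 60, 24 h replicates 3 and 5 gave 18 and 14) and 7 to 20 for males at 3 weeks against 24 h (24 h replicate 4 gave 20). For both sexes at 24 h it was 160 to 732 (female 24 h replicates 1, 6 and 8 gave 287, 270 and 732, male 24 h replicates 1, 3 and 6 gave 232, 160 and 223), and at 3 weeks 0 to 0. For the sexes it was 114 to 485 in naive animals (female replicates 2 and 5 gave 202 and 203, male replicates 1 and 2 gave 114 and 140), 2 to 97 at 24 h (female replicates 1 and 2 gave 97 and 13, male replicates 1 and 2 gave 8 and 6) and 2238 to 3183 over all conditions. At 3 weeks it was 92 to 956 (female replicates 2, 3, 5, 6, 7 and 8 gave 224, 202, 216, 956, 224 and 835, male replicates 1 to 5 gave 145, 92, 936, 136 and 103). For the sex difference of the 24 h change it was 0 to 11, and 20 libraries moved it. The count was 0 without naive female replicates 3 or 8, naive male replicates 1 or 3 or male 24 h replicates 4 or 5, 1 without naive female replicate 5 or female 24 h replicates 5, 6 or 10, and 2 without naive female replicates 1 or 7 or naive male replicate 4. It was 3 without female 24 h replicates 7 or 9, 4 without naive female replicate 2, female 24 h replicates 1 or 3 or male 24 h replicate 2, and 11 without female 24 h replicate 2. For the sex difference of the 3 week change it was 0 to 0.

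Avpr1a differences near 0 changed sign when a library was left out: for both sexes at 24 h the range was -0.19 to 0.11, for females at 3 weeks against 24 h -0.75 to 0.02 and for males at 3 weeks against 24 h -0.14 to 0.33. The sex difference of Avpr1a at 3 weeks passed without female 3 week replicate 8 (2.18) and with array weights (2.33, adjusted p = 0.0132).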

Other observations

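The relations with library position were fixed before their results were seen, and the tests with the Avpr1a-associated score were chosen after.

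The library spread of the values of 1 read, a measure of how strongly the normalization differed between genes, averaged 0.082 ± 0.025 log2 (SD, n = 6) in naive males and 0.071 ± 0.017 (n = 5) in males at 3 weeks, against 0.029 ± 0.016 (n = 6) in males at 24 h and 0.035 ± 0.008 (n = 10), 0.036 ± 0.013 (n = 10) and 0.040 ± 0.023 (n = 9) in naive, 24 h and 3 week females. Depth did not part the patterns: it was 27.9 ± 5.2 M reads (M for mega; n = 32) in pattern A and 29.2 ± 4.0 M (n = 14) in pattern B.

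Within groups of females at 24 h and 3 weeks and males at 24 h, the score of the 330 naive genes and the position of the library between the patterns had Pearson's r = -0.27 (permutation p = 0.22, Spearman's rho = -0.33, permutation p = 0.13, n = 25) and -0.20 without the 2 farthest libraries. For the 35 genes of males at 24 h across the 29 females the values were r = 0.23 (permutation p = 0.26), rho = 0.27 (permutation p = 0.17) and 0.28. Both had an adjusted p of 0.26 over 5 relations.

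More genes passed at 24 h once the axis that Avpr1a marks was taken out. With its score as a covariate, 99 genes outside the score passed for females at 24 h in place of 19, 92 for males in place of 34 and 644 for both sexes in place of 440, and all of the earlier genes were among the later ones in each of the 3. The median SE of females went from 0.096 to 0.090. The first component of the residuals within groups held 9.8% of their variance and correlated with Avpr1a at an absolute r of 0.78.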
